A study of Mus musculus with 12 samples.

How the data were processed

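Gene expression was measured in quadriceps muscle on 12 one-colour Agilent mouse arrays, each hybridised with RNA of a different mouse. Per the labels the animals were 13-week-old C57BL/6J males, of which 6 had trained on a treadmill for 4 weeks and 6 had stayed sedentary. The muscle of the trained mice was taken 3 hours after their last bout. The labels give no clock time for either group.

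The deposited scanner files give spot intensity on a linear scale. Per the file headers the authors extracted 12 of 12 arrays with Agilent Feature Extraction 10.5.1.1, whereas the submitters' notes name version 9.1, and the headers are taken as the record. The processed signal used here was already background-subtracted and detrended within each array, and no scaling between arrays had been applied. The deposited table of values has 41250 rows, of which 41174 are gene probes and 76 are others. For probes with a single spot, 100% of its values lay within 0.1% of the processed signal of the same array. How the authors combined the spots of a repeated probe is not stated. The table was therefore used only as an alternative source of values.

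Spots with outlier marks and control spots were left out, and spots of 1 probe were averaged. The signal was taken to log2, and each array's 75th percentile was subtracted. A probe was kept if it was well above background on at least 6 of the 12 arrays, which left 22916 of 41174 gene probes. Probes were named through the current gene table where their accession allowed it (26876 probes), otherwise by the name in the file, so that 28902 carried a gene symbol. Each gene was represented by its probe with the highest mean level, which gave 16494 genes and unnamed probes, 12810 of them with a symbol. Positions are those of the array annotation on genome build mm9. They were not checked against a sequence.

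Exercised was compared with sedentary by a moderated linear model in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table), without a block. P values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p below 0.05. Fold changes are differences of log2 means, with 95% intervals from the same model. Gene lists numbered 37 and were written down from general knowledge of muscle and its other cell types. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. A list needed at least 5 measured genes, which left 36 lists; the neutrophil list had 2 and was not tested. Each list's count of genes is given over all genes tested and also adjusted over the list alone. The distance between the group means over all genes was compared with all 924 assignments of 6 of the 12 arrays, as a one-sided exact permutation test. The titles number the mice within sets named 1 and 2 of unstated meaning, and a difference in the training effect between these sets was tested as an interaction in limma. The list score of an array is the mean deviation of the list's genes from their 12-array means.

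Genes were named by a rule: the 10 largest changes in each direction among called genes with a symbol and a probe above background on all arrays of a group, the 4 members with the smallest p of the 8 lists with the smallest camera p, 2 members of each other list with a called gene, and 12 genes chosen in advance. This gave 76 named genes. Nr4a3, among the 12 chosen in advance, was above background on 0 of 12 arrays and has no fold. These choices, the lists and most alternatives were made before the data were examined. Any other gene in the text is said to have been chosen after its values were seen. Of the lists, 26 are reported singly: those shifted, those with a called gene, and those on fibre type, energy metabolism and adipocytes. This grouping of the lists was made after the results were seen.

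The 12 arrays lay on 3 slides, with 1 exercised and 3 sedentary arrays on slide 1, 3 and 1 on slide 2, and 2 and 2 on slide 3. Fits with slide as a block and within each slide are therefore given beside the results. Other alternatives were quantile and median scaling, normexp background correction, the deposited table, other probe filters, kept outlier marks and all probes or their mean. Further alternatives were other variance models, array weights, an adjusted p below 0.10 and other list tests. The title set was used as a block, and each array was left out in turn. Another fit kept only the arrays whose set and animal number occur in both groups, with that shared number as a block. Added after the data had been seen were a normexp correction with limited background, scores of adipocyte and tendon lists as covariates, the removal of both sedentary arrays low in slow-fibre genes, an exact permutation of list means, and a permutation of the arrays within slides.

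The pipeline was tested on simulated data built from the arrays. It called 31 of 67 genes shifted by a log2 of 0.5, 62 of 67 shifted by 1 and 65 of 66 shifted by 2, along with 11 of 16199 unshifted genes, or 6.51% of its calls. Of the lists, it called 6 of 6 shifted and 0 of 30 unshifted ones. The simulated genes varied independently of one another, and the lists were drawn at random. The simulation therefore does not test list calls where genes vary together, as they can in the arrays. The number of arrays, 6 in each group, limits the precision.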

Results

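The data are array profiles of quadriceps from 6 mice after 4 weeks of treadmill training and 6 sedentary mice. The groups were alike on average in the measures of array quality compared here, though single arrays stood out, as given below. Probes well above background numbered 23168 ± 964 (SD, n = 6) in exercised and 23031 ± 1186 in sedentary mice, and the 75th percentile of the signal was 206 ± 20.1 against 190 ± 24.9 units of intensity. Neither measure differed by a two-sided exact permutation test (p = 0.814 and p = 0.229). Correlations between arrays across genes, which are not independent replicates, ran from 0.984 to 0.993 within exercised, from 0.986 to 0.993 within sedentary and from 0.978 to 0.992 between groups. The comparison asks which transcripts differ between trained muscle, 3 hours after a last bout of running, and muscle of sedentary mice. The design holds trained mice after a bout only, so an effect of the last bout and an effect of the 4 weeks are not separated.

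Among the largest rises in exercised muscle were those of Hspa1b and Hspa1a, which encode inducible heat shock proteins and were 9.26-fold (95% interval 3.98 to 21.6) and 8.63-fold (4.02 to 18.5) higher. Ddit4, an inhibitor of mTORC1 signalling, was 8.68-fold higher (4.86 to 15.5), the nuclear receptor gene Nr4a2 8.61-fold (4.91 to 15.1) and the transcription factor gene Atf3 8.17-fold (5.03 to 13.3), each with n = 6 and 6. Slc25a25, a mitochondrial carrier gene, rose 6.02-fold, Arrdc2 5.93-fold, Fam107a 5.23-fold, Otud1 5.03-fold and the metallothionein gene Mt2 4.66-fold. The 10 largest falls were smaller, from 3.43-fold for Akap5, a kinase anchor, to 2.26-fold for Trp53i11. They included Aplnr, the apelin receptor gene (2.80-fold, 1.77 to 4.42), the sialyltransferase gene St8sia4 (2.58-fold, 2.11 to 3.16), Arhgap18 (2.36-fold), Sema6a (2.45-fold) and Apol10b (2.32-fold). Others were Cd247, which encodes a T-cell receptor chain (2.72-fold), and the prostaglandin receptor gene Ptger4 (2.53-fold). Several of these were dim in exercised muscle, where Akap5 and Ptger4 were above background on 2 of 6 arrays, Cd247 on 3, and Sema6a, Apol10b and Trp53i11 on 5. Their folds are therefore imprecise. Hspa1a and Hspa1b are near-identical in sequence, and it was not tested whether their probes separate them.

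**Figure D1:**
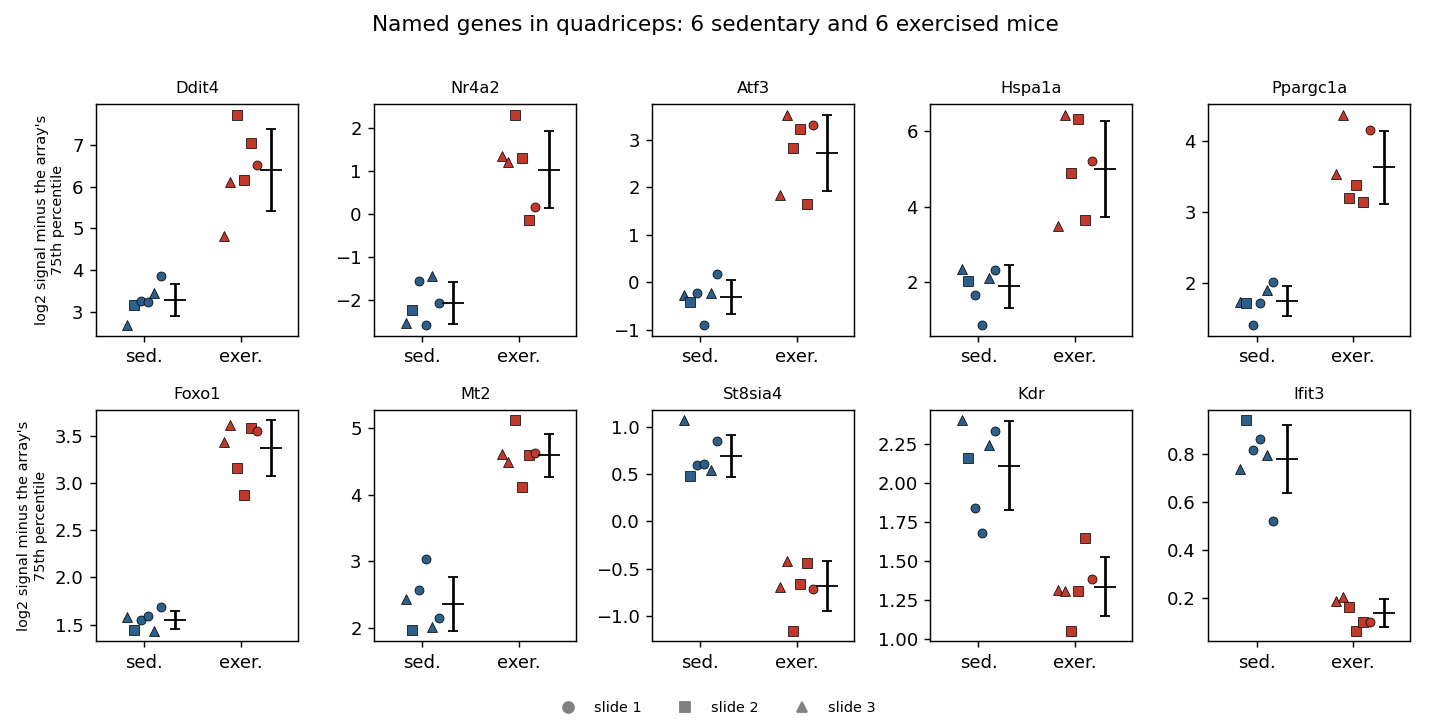
Level of 10 named genes on each array, as log2 signal minus the array's 75th percentile, in 6 sedentary (blue) and 6 exercised (red) mice; marker shapes give the slide, and bars are the mean ± 1 SD. For all 10 genes the lowest and highest arrays of the groups do not overlap, with Ddit4, Nr4a2, Atf3, Hspa1a, Ppargc1a, Foxo1 and Mt2 higher and St8sia4, Kdr and Ifit3 lower in exercised muscle.

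In all, 601 of 16494 genes and unnamed probes changed, 299 higher and 302 lower (limma, adjusted p below 0.05), and 483 of them had a symbol. A change of 2-fold or more was met by 75 of the higher and 23 of the lower, and the median size on the log2 scale was 0.72 among higher and 0.55 among lower ones. The median over all genes was -0.03. Groups did not overlap in 495 genes (3.001%, against 0.216% expected by chance), 407 of which were among the 601. Of the 76 named genes, 46 were past the threshold. Adjusted p was 0.00756 for Hspa1b, 0.000779 for Ddit4, 0.00501 for Hspa1a, 0.000625 for Nr4a2, 0.000315 for Atf3, 0.0175 for Aplnr and 0.000179 for St8sia4. With slide as a block these became 0.0375, 0.00257, 0.028, 0.00648, 0.0024, 0.0332 and 0.00162. Mt2, Foxo1 and Fam107a had adjusted p of 7.05e-05, 2.8e-05 and 2.8e-05, and 0.000604, 0.0002 and 0.000356 with the block. On the mm9 annotation the probe for Ddit4 (A_51_P245796) lies on chromosome 10 from 59412486 to 59412545 and that for Atf3 (A_52_P452689) on chromosome 1 from 192994547 to 192994606. Those for Nr4a2 (A_52_P494622) and St8sia4 (A_51_P236267) lie on chromosome 2 from 56960699 to 56960758 and on chromosome 1 from 97484331 to 97484390.

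The slides bear on this count. With slide as a block 349 genes changed (193 higher, 156 lower), 326 of them shared with the 601, and the blocked log2 values were a median of 0.988 times the unblocked ones. Within slides 1, 2 and 3, 0, 8 and 0 genes passed in limma (1010, 970 and 2143 at an unadjusted p below 0.05). Slide 1 has 1 exercised and slide 2 has 1 sedentary array, which is assumed to vary like the other group, so these counts say little about the 601. The sign of all 601 was the same in each of the 3 slides, which is in part built in because the genes were picked on these arrays. Among the 46 named genes, 38 passed with the block, and Cd247, Ptger4, Hsp90aa1, P4ha1, Flt1, Trim63, Nfe2l2 and Fhl3 did not. Of 100 drawn splits of the arrays into 6 and 6, the real split alone reached 601 genes, and the highest other split reached 53. These splits did not hold slide fixed.

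Glucocorticoid-responsive genes rose as a group. Of 15 measured members 9 rose, 0 fell and 6 did not pass; adjusted over the list alone, 11 rose. Ddit4 and Mt2 are given above, and the transcription factor gene Cebpd rose 3.22-fold (95% interval 2.45 to 4.24, n = 6 and 6), Mt1 2.91-fold (2.24 to 3.79) and Cebpb 2.15-fold (1.81 to 2.54). Chosen after their values were seen, Fkbp5 and Tsc22d3, both textbook targets of the glucocorticoid receptor, rose 2.68-fold and 1.99-fold. The list's median was 0.99 on the log2 scale, and 0.63, 0.96 and 1.17 within slides 1, 2 and 3. Its camera adjusted p was 5.37e-19, or 1.03e-16 with slide as a block, and this shift held with an estimated correlation, adjusted p = 0.0133 with an estimated correlation. The exact permutation test of the list mean gave p = 0.00216, the smallest p these permutations can give (0.026 adjusted).

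Heat shock genes and chaperones also rose as a list, with 7 of 25 members higher, 0 lower and 18 not passing; adjusted over the list alone, 13 rose. Besides Hspa1a and Hspa1b these included the co-chaperone gene Dnaja1 (2.16-fold, 1.61 to 2.90, n = 6 and 6) and Hsp90aa1 (2.12-fold, 1.5 to 2.99). The constitutive Hspa8, chosen after its value was seen, did not pass (log2 difference 0.06). Medians within slides were 0.30, 0.27 and 0.27. The camera adjusted p of 4.46e-11 (8.81e-10 with slide as a block) was lost with an estimated correlation, where adjusted p = 0.389 with an estimated correlation.

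Among immediate early genes the picture was uneven. Of 21 measured members 7 rose, 0 fell and 14 did not pass; adjusted over the list alone, 10 rose and 2 fell. Maff rose 4.30-fold (95% interval 3.12 to 5.93, n = 6 and 6) and the kinase gene Sik1 4.33-fold (3.05 to 6.14), beside Nr4a2 and Atf3. Nr4a1, named in advance, did not pass (log2 difference 0.49, adjusted p = 0.0969), and neither did Egr1 (-1.36) or Fos (0.21), which were chosen after their values were seen. The list's medians within slides were 0.35, 0.52 and 0.39. Its camera adjusted p was 5.35e-07 (0.000121 with slide as a block), but adjusted p = 0.389 with an estimated correlation.

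Few genes of energy metabolism passed. Ppargc1a, the coactivator of mitochondrial biogenesis, was 3.68-fold higher (95% interval 2.70 to 5.04, adjusted p = 0.000388, and 0.000669 with slide as a block). The forkhead transcription factor gene Foxo1 was 3.53-fold higher (2.94 to 4.24), and the glycogen-targeting subunit gene Ppp1r3c 2.0-fold (1.53 to 2.62), each with n = 6 and 6. Ppargc1a was the only one of 26 genes for mitochondrial biogenesis and dynamics past the threshold, and Ppp1r3c the only one of 30 for glucose uptake, glycolysis and glycogen; adjusted over the list alone the counts were 1 and 2. No member passed among 79 subunits of oxidative phosphorylation, 19 genes of the tricarboxylic acid cycle and 29 of fatty acid uptake and oxidation, and adjusted over the list alone the count stayed 0 in all 3 lists. These lists did not pass, with camera adjusted p of 0.352 for biogenesis, 0.754 for glucose, 0.415 for oxidative phosphorylation, 0.0605 for the cycle and 0.245 for fatty acid oxidation. With slide as a block, oxidative phosphorylation (0.00102) and the tricarboxylic acid cycle (0.0137) passed as higher. Medians within slides 1, 2 and 3 were -0.01, -0.02 and 0.17 for oxidative phosphorylation. For the cycle they were -0.01, 0.03 and 0.16, so both rises lay mainly in slide 3. Neither list passed with an estimated correlation and no block (camera adjusted p = 0.947 and 0.774). Over 35 alternatives the cycle passed as higher in 13, among them quantile scaling (0.00642), array weights (0.0288), the title set as a block (0.029) and the fit without exercised s2m4 (0.00519). Oxidative phosphorylation passed as higher in 7 and, with the brown adipocyte score as a covariate, as lower (0.0336). Fatty acid oxidation passed as higher without sedentary s1m1 (0.0154). Pdk4 (log2 difference -0.29), Hk2 (0.22), Ucp3 (0.31) and citrate synthase Cs (0.01), all named in advance, did not pass. Ppargc1b (-0.31) did not pass either, and another of its probes gave 0.0015.

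Ubiquitin ligases and autophagy genes were shifted higher as a list, with 2 of 22 members higher (3 adjusted over the list alone), 0 lower and 20 not passing. The members past the threshold were Foxo1 and Trim63 (1.36-fold, 1.15 to 1.61), a muscle ubiquitin ligase gene also called MuRF1. Trim63 had an adjusted p of 0.0475 and stayed past the threshold in 2 of the 12 fits that left out an array (adjusted p up to 0.1). The list's median was 0.06, with -0.04, 0.07 and 0.19 within slides. Camera gave an adjusted p of 0.00763 (0.00236 with slide as a block, 0.0698 with the brown adipocyte score as a covariate), and adjusted p = 0.708 with an estimated correlation.

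Genes for mechanical load and sarcomere repair were shifted higher, with 2 of 23 members higher, 1 lower and 20 not passing; adjusted over the list alone, 5 rose and 1 fell. Abra, an activator of muscle serum-response signalling, rose 1.86-fold (1.45 to 2.38, n = 6 and 6), and Fhl3 fell 1.28-fold (1.14 to 1.44). The call for Fhl3 was kept in 5 of the 12 fits that left out an array. Medians of this list within slides were 0.18, 0.17 and 0.17. Its adjusted p was 0.00911 (0.00618 with slide as a block), and adjusted p = 0.613 with an estimated correlation. It was 0.146 with the brown adipocyte score and 0.16 with the tendon score as a covariate.

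Vascular genes moved in both directions. Kdr, which encodes the main VEGF receptor, fell 1.71-fold (95% interval 1.40 to 2.09, adjusted p = 0.00676, or 0.0179 with slide as a block), whereas Flt1, which encodes another VEGF receptor, rose 1.33-fold (1.18 to 1.51, adjusted p = 0.0144, or 0.0553 with the block). Of 20 measured genes of angiogenic signalling 2 rose and 3 fell (3 and 4 adjusted over the list alone). Of 17 endothelial markers 2 rose and 3 fell (4 and 5). Kdr and Flt1 belong to both lists and are counted in each. Vegfa, named in advance, had a log2 difference of -0.15 and did not pass; its other probes gave 0.20 and 0.18. Of 13 smooth muscle and pericyte markers 3 rose and 1 fell (3 and 2 adjusted over the list alone), with the contractile gene Cnn1 1.88-fold higher (1.5 to 2.36) and the channel gene Kcnj8 1.54-fold lower (1.28 to 1.85). None of the 3 lists was shifted one way by camera (adjusted p = 0.217, 0.862 and 0.58). The angiogenic list passed as lower with the tendon score as a covariate (0.00327) and without both sedentary arrays low in slow-fibre genes (0.0359).

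Clock genes changed in both directions as well, 3 of 19 higher and 4 lower (4 and 6 adjusted over the list alone), with no shift of the list (camera adjusted p = 0.818). The repressor gene Nfil3 rose 2.85-fold (95% interval 2.32 to 3.49, adjusted p = 9.17e-05, and 0.000881 with slide as a block) and Bhlhe41 fell 1.38-fold (1.24 to 1.54). Chosen after their values were seen, Per1 and Per2 rose 2.67-fold and 2.05-fold, while Nr1d1, Dbp and Bhlhe40 fell 2.03-fold, 1.77-fold and 1.54-fold. With slide as a block Dbp (adjusted p = 0.0524) and Bhlhe40 (0.068) no longer passed. Among satellite cell and regeneration genes 2 of 19 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.241). Myog, a myogenic transcription factor gene, rose 2.30-fold (1.82 to 2.90, adjusted p = 0.00105, and 0.00767 with slide as a block) and Sdc4 1.34-fold (1.18 to 1.52). Dok7, needed for the neuromuscular junction, rose 1.47-fold (1.26 to 1.71), as the only one of 16 genes of that list to pass (1 adjusted over the list alone; camera adjusted p = 0.58). Nfe2l2, a regulator of antioxidant genes, rose 1.46-fold (1.20 to 1.77) as the only one of 23 antioxidant genes (1 adjusted over the list alone; camera adjusted p = 0.297). The call for Nfe2l2 (adjusted p = 0.0397) was kept in 3 of the 12 fits that left out an array.

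Interferon-response genes were lower as a list. All 26 measured members had a log2 difference below 0, with a median of -0.26, but 1 passed: Ifit3 fell 1.56-fold (95% interval 1.40 to 1.74, adjusted p = 0.000406, and 0.00257 with slide as a block). Adjusted over the list alone, 2 fell. Oasl2, Mx2 and Isg15 had log2 differences of -0.58, -0.47 and -0.40 and did not pass. Medians within slides were -0.23, -0.10 and -0.54. The list's adjusted p was 0.000979 (0.000387 with slide as a block), but adjusted p = 0.726 with an estimated correlation. It was 0.246 with the tendon score as a covariate.

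Some lists of markers for tissue other than muscle fibres were shifted by camera too. Tendon cell markers were shifted higher, with 10 of 10 above 0 and a median log2 difference of 0.82. None passed over all genes, and 9 rose adjusted over the list alone. Tnmd, Comp, Fmod and Kera had differences of 1.11, 1.1, 0.92 and 0.91 (SE 0.385, 0.387, 0.296 and 0.317). The tendon score was 0.39 ± 0.51 (SD, n = 6) in exercised and -0.39 ± 0.54 in sedentary mice. Medians within slides were 1.39, 0.42 and 0.38. The list's adjusted p was 6.45e-06 (0.000347 with slide as a block), and adjusted p = 0.657 with an estimated correlation. Collagen and extracellular matrix genes were also shifted higher as a list, with 23 members above 0 and 15 below. Of 38 members 2 passed as higher, 0 as lower and 36 did not pass (4 higher and 1 lower adjusted over the list alone). Ccn2, a matricellular growth factor gene, rose 3.03-fold (2.03 to 4.53, adjusted p = 0.00584, and 0.0157 with slide as a block), and the collagen hydroxylase gene P4ha1 rose 1.33-fold (1.15 to 1.53) with a call kept in 3 of the 12 fits that left out an array. The collagen list's adjusted p was 0.00521 (0.0174 with slide as a block, slide medians 0.22, 0.07 and 0.08), and adjusted p = 0.79 with an estimated correlation. It was 0.139 without sedentary mouse s2m2, and the direction turned when the tendon score was a covariate (0.0337). Schwann cell and nerve markers were higher with an adjusted p of 0.0266 and 0 of 9 members past the threshold, also adjusted over the list alone, and adjusted p = 0.708 with an estimated correlation. That call was lost with slide as a block (0.0832; slide medians 0.00, 0.23 and 0.17) and without exercised s1m1 (0.0766), exercised s2m3 (0.11) or sedentary s1m6 (0.0609). It was also lost with the tendon score as a covariate (0.253), a trended and robust variance (0.0583) and the mean of probes (0.0555), and 24 of 35 alternatives kept it.

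Fatty acid synthesis genes were shifted higher, although 0 of 18 members passed and 1 fell adjusted over the list alone. Fasn and Acly, lipogenic enzyme genes, had log2 differences of 1.35 (SE 0.54) and 1.13 (SE 0.355), while Gpam had -0.33. The list's median was 0.33, with 0.58, 0.28 and 0.22 within slides. Its adjusted p was 0.00496 (0.00399 with slide as a block), and adjusted p = 0.774 with an estimated correlation. Adipocyte transcripts varied widely between arrays: Ucp1, the brown fat uncoupling protein gene, ran from -7.15 to 3.25 and Cidea from 0.56 to 5.41 on the log2 scale, both chosen after their values were seen. The brown adipocyte score was 0.53 ± 0.84 (SD, n = 6) in exercised and -0.53 ± 0.67 in sedentary mice. It rested mainly on Ucp1 (log2 difference 4.35, above background on 5 of 6 exercised and 2 of 6 sedentary arrays) and Cidea (1.79), since the other 4 members ran from -0.10 to 0.18 and the list's median was 0.14. With most sedentary arrays not above background, the difference of Ucp1 is imprecise, and so is the score. The white adipocyte score was 0.12 ± 0.59 in exercised and -0.13 ± 0.64 in sedentary mice. Neither adipocyte list had a member past the threshold (0 of 6 and 0 of 13, also adjusted over the list alone), and neither list passed (camera adjusted p = 0.127 for both), but with slide as a block the brown list passed (0.0319). Over 35 alternatives the brown list passed as higher in 7 and the white list in 13, the latter with the deposited table (0.0473), array weights (0.0178), the tendon score as a covariate (0.000252) and without sedentary s2m2 (0.00846), for example. With the brown adipocyte score as a covariate the adjusted p of fatty acid synthesis was 0.832.

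**Figure D2:**
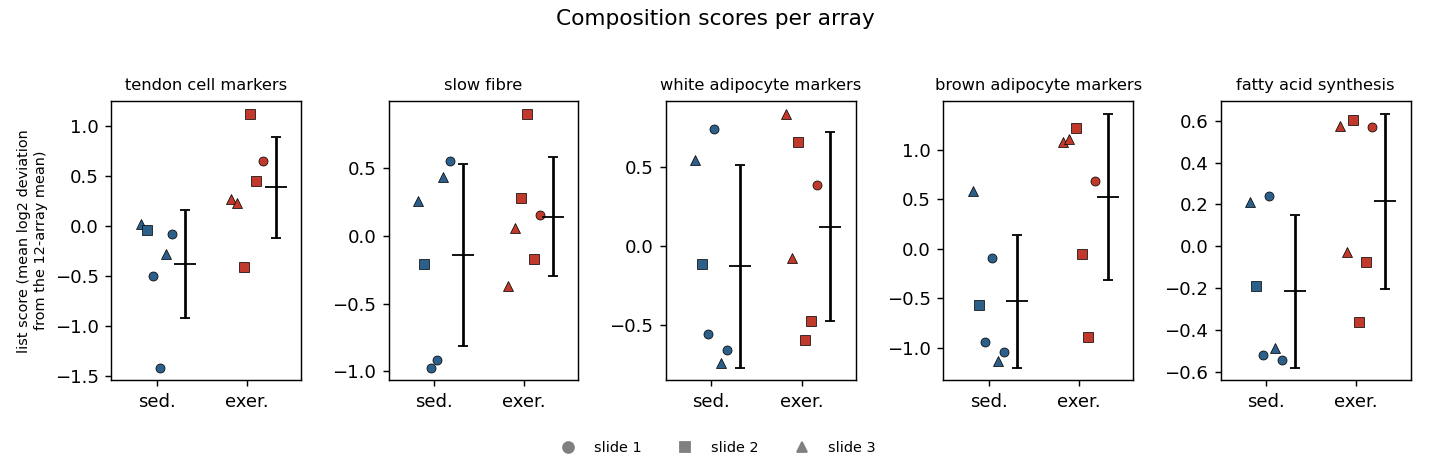
Score of 5 gene lists on each array (mean log2 deviation from the 12-array mean) in 6 sedentary (blue) and 6 exercised (red) mice; marker shapes give the slide, and bars are the mean ± 1 SD. Sedentary s2m2 has the lowest tendon score (-1.42), and the groups overlap in all 5 lists.

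As a list, contractile genes of fast fibres were shifted lower by camera, by a small amount. Of 14 measured members 13 were below 0, with a median log2 difference of -0.18, and 0 passed; adjusted over the list alone, 1 fell. Tnnc2, Myh4 and Myl1 had differences of -0.23, -0.18 and -0.19. Their sign turned with normexp background correction (0.03, 0.09 and 0.10), which failed on some arrays. The list's adjusted p was 0.00763, and adjusted p = 0.774 with an estimated correlation. This call was lost with slide as a block (0.0819, slide medians -0.17, -0.26 and 0.08) and with quantile scaling (0.792). The tendon score as a covariate (0.373) and a block over the arrays with shared numbers (0.548) also lost it. The direction turned with normexp (0.376), but with the background limited the call was kept (0.0486). It was also lost without both sedentary arrays low in slow-fibre genes (0.208), s1m6 and s2m2, which had the highest fast-fibre scores of the 12 arrays (0.22 and 0.25). In all, 25 of 35 alternatives kept the call. Slow-fibre contractile genes did not pass as a list (camera adjusted p = 0.062, 0.231 with slide as a block). Of its members 0 of 12 passed, also adjusted over the list alone. Medians within slides were 0.66, 0.72 and -0.75, so slide 3 went the other way. The list passed as higher in 13 of 35 alternatives, among them median centring (0.043), quantile scaling (0.0457), the mean of probes (0.0256) and the fit without sedentary s2m5 (0.00872). Its direction turned in 3, of which the block over the arrays with shared numbers passed as lower (0.0195). That fit left out exercised s2m1 and s2m3 and sedentary s1m6 and s2m2, with slow-fibre scores of 0.28, 0.90, -0.97 and -0.92. The block and the missing arrays are therefore not told apart. The slow-fibre score was 0.14 ± 0.44 (SD, n = 6) in exercised and -0.14 ± 0.67 in sedentary mice. Myh7, Myh2 and Myh1, myosin heavy chain genes named in advance as was Myh4, had log2 differences of 0.61 (SE 0.594), 0.03 (SE 0.117) and 0.06 (SE 0.0893) and did not pass.

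**Figure D3:**
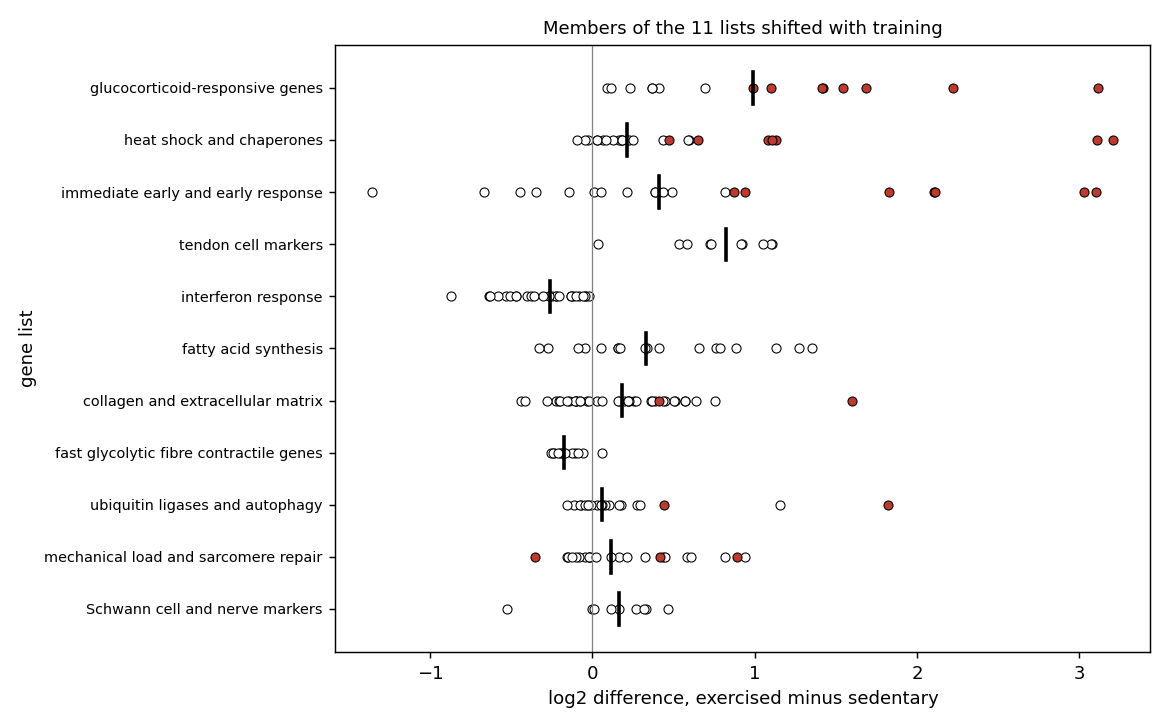
Log2 difference, exercised minus sedentary, of each measured member of the 11 lists shifted by camera; filled points passed the threshold over all genes, and the vertical bar is the list's median. Members above 0 number 15 of 15 for glucocorticoid-responsive genes and 10 of 10 for tendon markers, and 26 of 26 are below 0 for the interferon response. The fast-fibre direction turned with normexp, which failed on some arrays.

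Of 36 lists tested, 11 were shifted by camera, 9 higher and 2 lower, and 12 with slide as a block. With an estimated correlation the glucocorticoid list alone held, and by exact permutation of list means 4 did: glucocorticoid, heat shock, immediate early, and ubiquitin and autophagy. The number of shifted lists was not exceptional: 39 of 100 drawn splits of the arrays into 6 and 6 shifted as many, the real one included, with a median of 10 and a highest of 17 among the others. In 10 further lists (branched-chain amino acid breakdown, the unfolded protein and integrated stress response, erythroid, lymphocyte, macrophage and monocyte, and fibro-adipogenic progenitor markers, the cell cycle, calcium handling, secreted muscle factors, and heme and iron handling), 0 genes passed and adjusted p ran from 0.0955 to 0.931.

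Among filtered genes, the profiles of the groups as a whole were farther apart than under other assignments of the arrays. The distance between group means was 35.0 against a median of 24.1 over 924 assignments and a next highest of 32.0. The one-sided exact permutation p was 0.00216, the smallest these assignments can give, and 0.00286 when arrays were permuted within title sets only. Permuted within slides only, a test added after the data had been seen, the exact p was 0.0104, the smallest its 96 assignments can give, with a next highest distance of 30.7. It was 0.673 with normexp background correction, which failed on 4 arrays. With no filter on dim probes it was 0.0476, with 44 of 924 assignments, the real one included, at least as large.

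The sets 1 and 2 in the titles were compared to ask whether training acted differently in them. No gene differed in its response between the sets (0 genes in limma, 1434 at an unadjusted p below 0.05, lowest adjusted p = 0.527), and 11 alternatives also gave 0. All 601 genes had the same sign in both sets, which is again in part built in. Within set 1, with 2 exercised and 3 sedentary mice, 0 genes passed (1771 at an unadjusted p below 0.05), and within set 2, with 4 and 3, 36 did. With 2 to 4 mice in each group of a set, a difference could have been missed.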

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

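The tests of adipocyte scores, tendon markers, the array low in tendon markers, slide and clock genes were chosen after the results they bear on had been seen, and the counts of splits before. In 17 of 210 sets of 6 values (8.1%, where chance gives about 1 in 20) 1 array lay far from the other 5. Sedentary s2m2 was that array 5 times and exercised s2m1 4 times.

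Among genes, on the log2 scale and with the range of the other 5 arrays in parentheses, exercised s2m1 was far below for Aplnr (-2.05, others -0.75 to -0.145) and Sema6a (-5.21, others -4.34 to -4.005). Exercised s1m5 was far below for Arhgap18 (-3.07, others -2.56 to -2.32) and far above for Nfil3 (4.20, others 3.42 to 3.61). Exercised s2m5 was far above for Tnnc2 (10.79, others 10.58 to 10.63). Sedentary s2m2 was far below for Dnaja1 (2.18, others 2.70 to 2.997), Fmod (2.17, others 3.37 to 3.96) and Tnmd (-1.51, others 0.20 to 1.15). Sedentary s1m6 was far below for Myh2 (9.02, others 9.55 to 9.76). Among list scores, exercised s2m1 was low for collagen genes (-0.38, others 0.10 to 0.23) and high for glucocorticoid-responsive genes (0.89, others 0.37 to 0.54). Exercised s2m3 was low (-0.21) and sedentary s1m1 high (0.33) for fatty acid uptake and oxidation. Sedentary s2m2 was low for tendon markers (-1.42, others -0.51 to 0.02) and angiogenic signalling (-0.19, others 0.04 to 0.16), and sedentary s1m6 for the neuromuscular junction (-0.11, others -0.01 to 0.03). The 75th percentile of the signal was highest in sedentary s2m5 (237, others 167 to 191).

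For the 601 genes changed with training, 1 of 100 drawn splits, the real one, gave as many, and the highest of the others gave 53. So many calls are thus unlikely from a random division of the arrays, but the splits did not hold slide fixed. Splits that mix the groups also carry the group difference in their error, which tends to lower their counts. With slide as a block 349 genes changed. For the 11 shifted lists chance cannot be excluded: 39 of 100 splits, the real one included, shifted as many, and the highest of the others shifted 17. The list calls lean on a preset correlation between genes, and with an estimated correlation the glucocorticoid list alone held (adjusted p = 0.0133).

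The fatty acid synthesis list was higher in exercised mice. With the white adipocyte score as a covariate it stayed past the threshold at the preset correlation (camera adjusted p = 0.000346). Without the covariate it did not pass with an estimated correlation (adjusted p = 0.774), directional fry (0.495) or exact permutation of list means (0.305). These tests were not rerun with the white score, so white fat is not excluded. With that score the list's median log2 difference went from 0.33 to 0.29 and that of Fasn from 1.35 (SE 0.54) to 0.94 (SE 0.149). The effect thus shrank somewhat, and the error of Fasn fell more, so the lower p does not mean a larger effect. With the brown adipocyte score the list did not stay past the threshold (adjusted p = 0.832). Its median log2 difference went from 0.33 to 0.02 and that of Fasn from 1.35 (SE 0.54) to 0.22 (SE 0.447). The call therefore ended because the effect shrank and not because the error grew. Over 35 alternatives the list's adjusted p ran from 4.44e-07 (normexp, which failed on some arrays) to 0.832 (the brown score). Brown fat in some samples is thus a candidate explanation, but the score rests mainly on Ucp1 and Cidea, chosen here after their values were seen (differences of 4.35 and 1.79, levels from -7.15 to 3.25 and from 0.56 to 5.41), while the other 4 measured markers ran from -0.10 to 0.18; 2 of the 6 also belong to other lists and 5 were above background on all arrays. A response of the muscle itself, or of fat within it, to training stays open and untested.

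Tendon cell markers were also higher in exercised mice. Leaving out sedentary s2m2 kept the call at the preset correlation (camera adjusted p = 2.20e-05, median log2 difference from 0.82 to 0.59), so that call does not rest on this array alone. With all 12 arrays the list did not pass with an estimated correlation (adjusted p = 0.657), directional fry (0.239) or exact permutation of list means (0.143). These tests were not rerun without s2m2. Over 35 alternatives the adjusted p ran from 1.07e-18 (normexp, which failed on some arrays) to 0.948 (the tendon score as a covariate). That score is built from these same markers, so its outcome was fixed in advance. The deviations of the 10 markers from their group means went together, with a mean correlation of 0.743 between pairs of genes across the 12 arrays, against at most 0.265 in 1000 random lists of the same size. That is what differing amounts of tendon in the samples would give, but a joint change of genes within tendon cells would give it too. Random genes are no comparison with markers of another cell type, and the correlation includes the outlying sedentary s2m2. It therefore does not tell these accounts apart. More tendon tissue in exercised samples may account for the shift (Thbs4, chosen after its values were seen, 5.09 to 6.24 on the log2 scale, and 3.88 to 5.56 in sedentary samples). No marker belongs to another list, and all were above background on all 12 arrays. Detection in whole samples does not tell expression by muscle itself from tendon in each sample. A training effect on tendon cells stays open and untested.

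The glucocorticoid-responsive list had the strongest shift. With slide as a block it stayed (adjusted p = 1.03e-16, median log2 difference from 0.99 to 0.94), which argues against slide differences. Over 35 alternatives the adjusted p ran from 4.46e-43 (normexp, which failed on some arrays) to 0.026 (exact permutation of list means). The score was above 0 in 6 of 6 exercised and below 0 in 6 of 6 sedentary mice. Sampling at another time of day cannot be told apart from training: 6 of 18 clock genes outside this list passed, 2 higher and 4 lower, of which Dbp and Bhlhe40 did not pass with slide as a block (adjusted p = 0.0524 and 0.068), and the labels give no clock time. A hormonal response to the last bout is a biological possibility that no value here tests.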

How the results depend on the processing

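Alternatives chosen after the data had been seen were the limited normexp, the 3 score covariates, the joint removal of sedentary s1m6 and s2m2, the exact permutation of list means and the permutation within slides; the others were planned. Over their alternatives the 46 called genes gave 1327 values, of which 1134 kept direction and call, 193 kept the direction alone and 0 reversed. Other probes of 28 named genes numbered 35, of which 31 gave the same result, 1 lost the call and 3 reversed. The 11 shifted lists gave 385 values, 335 with direction and call, 48 with the direction alone and 2 reversed. Calls held in 35 of 35 alternatives for the glucocorticoid list, in 34 for the heat shock and immediate early lists, and in 24 for the Schwann cell list, the least. Of 349 values for the 10 lists reported together, 28 passed and 41 had the opposite direction. Except where an account is given, the cause of a change was not tested.

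The number of changed genes was 315 with no filter, which tests more genes, 1009 at an adjusted p below 0.10 and 349 with slide as a block. It was 297 and 296 with the brown adipocyte and tendon scores as covariates (237 and 228 shared with the 601) and 298 without both sedentary arrays low in slow-fibre genes. Leaving out 1 array gave 418 to 570. Normexp background correction gave 0 genes (limma, 0.649% at an unadjusted p below 0.05), 27 lists and a global p of 0.673. It failed on exercised s2m1 and s2m4 and sedentary s2m4 and s2m5, where 5 to 16 spots had strongly negative values (down to -599179) and the 1st percentile after correction was 730 to 2285, against 53.3 to 54.7 on the others. With the background limited it gave 476 genes, 421 of them shared with the 601, 22 lists and a global exact permutation p of 0.00216, the smallest possible.

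The number of shifted lists was 18 with no filter, 1 with an estimated correlation, 3 with directional fry, 17 with mixed fry, which counts change in either direction, and 4 by exact permutation. It was 11 to 18 without 1 array, with 17 without exercised s2m4 and 18 without sedentary s1m1.

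Animal numbers shared by the groups showed no clear pairing of the mice: across genes, the deviations of the same-number arrays correlated at 0.15, -0.19, 0.12 and 0.28, which ranked 2, 6, 3 and 1 among the 6 sedentary arrays. So few pairs cannot exclude a pairing. The s1m1 arrays also shared slide 3 and the s2m5 arrays slide 1. Deviations of exercised and sedentary arrays correlated at a mean of 0.12 on the same slide and -0.046 on others, so pairing and slide are mixed here. The replicate block over the 8 arrays with shared numbers gave 29 genes and 19 lists, with fewer arrays and degrees of freedom, and it is not read as a weaker effect. Under it the directions of the slow-fibre (adjusted p = 0.0195), glucose (0.689) and smooth muscle (0.767) lists turned, as did Pdk4 (log2 0.21), Myh7 (-0.70) and Myh2 (-0.16).

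Directions of other lists turned as follows, each with its adjusted p. The glucose list turned with quantile scaling (0.51), normexp (0.0013), limited normexp (0.605), the mean of probes (0.96), slide as a block (0.988), the tendon score (0.42) and without both low arrays (0.769), and ran from 0.296 to 0.982 without 1 array. Endothelial markers turned with normexp (0.429), limited normexp (0.887), the mean of probes (0.693) and the white (0.859) and brown (0.707) scores, and ran from 0.4001 to 0.98 without 1 array. Oxidative phosphorylation turned with fry (0.99), the exact permutation (1) and the brown score (0.0336), and ran from 0.0237 (without exercised s2m4) to 0.928. The brown score also turned fatty acid oxidation (0.8286) and white adipocyte markers (0.0511), and the tendon score turned collagen (0.0337), slow-fibre (0.524) and smooth muscle (0.668) genes. Without both low arrays the slow-fibre (0.769) and smooth muscle (0.985) lists turned. Normexp turned the fast-fibre list (0.376) and fry the clock list (0.979), which ran from 0.564 to 0.995 without 1 array.

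Of all 601 called genes 598 kept their sign with normexp, and 600 with limited normexp, the deposited table and kept outlier marks. The named genes that reversed had not passed the test. With normexp these were Tnnc2 (log2 0.029), Myh4 (0.090), Myl1 (0.096) and Vegfa (0.12). Other probes gave 0.20 and 0.18 for Vegfa and 0.0015 for Ppargc1b. Cs gave -0.013 with the white and -0.081 with the brown score, and -0.016 to 0.037 without 1 array. Myh7 gave -0.40 with the tendon score and -0.26 without both low arrays. Myh2 gave -0.031 with slide as a block, -0.056 with the brown score, -0.029 with the tendon score and -0.11 without both low arrays, and -0.078 to 0.069 without 1 array. Signal over background limits genes such as Akap5 and Ptger4, above it on 2 of 6 exercised arrays.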

Other observations

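Further members of the lists passed the test and lie outside the naming rule, so they were chosen after their values were seen. Btg2, an antiproliferative early response gene, was 3.54-fold higher in exercised muscle (95% interval 2.47 to 5.09, n = 6 and 6), and Ier5 and Klf4 were 1.92-fold and 1.83-fold higher. The co-chaperone gene Dnajb1 was 2.19-fold higher (1.52 to 3.17). Among vascular genes, Thbs1, an inhibitor of vessel growth, was 2.94-fold higher (1.73 to 4.999), whereas Vegfc was 1.55-fold lower (1.27 to 1.88). The endothelial tight junction gene Cldn5 was 1.82-fold lower (1.36 to 2.44) and Egfl7 1.49-fold lower, while the transcription factor gene Sox18 was 1.70-fold higher (1.34 to 2.14). Smooth muscle Myh11 and Mylk were 1.37-fold and 1.39-fold higher. Heyl, a Notch target gene, was 1.602-fold lower (1.26 to 2.03), and Anxa2, which takes part in membrane repair, 1.33-fold higher. With slide as a block, Btg2 (adjusted p = 0.00962), Ier5 (0.0327), Klf4 (0.0319), Dnajb1 (0.0452), Vegfc (0.0185), Heyl (0.0248) and Mylk (0.0498) passed, and Thbs1 (0.115), Cldn5 (0.0708), Egfl7 (0.0748), Sox18 (0.0579), Myh11 (0.134) and Anxa2 (0.0608) did not.

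Slides differed from one another. With the group in the model, limma found 265 genes that differed between slides (2364 at an unadjusted p below 0.05) and 0 that differed between the title sets (770 at an unadjusted p below 0.05).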
